A study of Oryza sativa with 72 samples.

How the data were processed

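RNA sequencing libraries were compared from leaves of the rice cultivar IR64, an indica variety. Per the labels, plants at 14 days after sowing were left to drain in raised pots for 9 days (severe drought) and were then watered for 6 days, while control plants stayed irrigated. The fully expanded latest leaf and the second latest leaf were sampled from both treatments at drought days 0, 6 and 9, at 2 h after watering resumed, and at days 3 and 6 of rehydration. This gave 24 groups of 3 libraries, 72 in all. Libraries were made from polyadenylated RNA with a directional kit, per the labels' protocols.

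The authors deposited raw read counts in a table of 55986 lines and 72 columns, with no normalisation. Reads were aligned with STAR and counted with featureCounts 2.0.0 on build IRGSP-1.0, per the submitters' processing notes. The STAR version, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The lines carry no gene identifier, and nothing in the sources used here pairs a line with a gene. Each line is therefore called a feature, named where needed by its place in the table. The 19 gene lists and the rule for naming genes that were fixed in advance need identifiers and were not applied, so 0 lists were tested. Features that share reads with near-identical copies or with an antisense partner could not be told from others. In all, 10219 features were at 0 in every library and 45767 had a count.

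Every column was matched to its sample by the library name in the labels, and 0 columns were left over. The labels number the replicates 1 to 3 in each group and do not state that they came from separate plants, so p-values measure the spread between these libraries, which may in part be technical. Total counts ran from 6370914 to 24192248 (median 13707163) in 71 libraries. The other library, treated replicate 2 of drought day 9 in the latest leaf, held 1755 counts over 1046 features, so that 1 count there equals 570 CPM (counts scaled to a common library total). It stayed in the fits because the design had been fixed with all libraries, and it was left out of means, scores and principal components. At the smallest usable total, 3 counts correspond to 0.471 CPM, and at the largest to 0.124 CPM, which covers counting error only.

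Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low-count features were removed by filterByExpr with the groups, and libraries were scaled by trimmed mean of M values (TMM). Quasi-likelihood models (glmQLFit, glmQLFTest) with 1 mean per group were fitted to the 36 libraries of each leaf position. All 72 libraries were fitted together for comparisons between leaf positions. Treated plants were set against controls of the same stage and leaf. Changes of the response between stages, and between leaf positions, were tested as interaction contrasts. Features with a Benjamini-Hochberg adjusted p under 0.05 were counted as called, and fold changes are fitted log2 values, treated over control. The tests, groups and most alternatives were fixed before the data were examined. Features called at drought day 9 were followed through later stages by counting those called again in the same direction, beside the number that independent lists would share. A score per library was the mean log2 CPM (prior count 2) of the features called higher at a stage minus that of the features called lower, and scores were compared by two-sided exact permutation tests. With 3 libraries against 3 the smallest p such a test can give is 0.1.

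On simulated counts with 200 features changed among 20184, the fit for drought day 9 in the latest leaf recovered 49.5% of the 2-fold and 95.1% of the 4-fold changes and called 7 unchanged features. For rehydration day 3 it recovered 63.9% and 96.1% in the latest leaf, among 20181 features. In the second latest leaf it recovered 64.3% and 96.1% among 20429 features at rehydration day 3, and 36.7% and 90.2% among 20459 for the change of response between day 9 and 2 h. For the comparison of leaf positions at 2 h, 38.8% and 91.2% were recovered among 20802 features. The changed features were drawn only from those above a set mean CPM. All groups otherwise shared the same means and, for each feature, the same spread, and libraries varied independently. The rates therefore do not cover features of low count, and may be too high for the real libraries.

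Replicates of a group were compared before averaging. None of the 70 pairs had identical values (0 pairs), and the chi-square per degree of freedom ran from 6.12 to 162, so no library was counted as a copy of another. Replicate numbers were checked for pairing by correlating each library's deviations from its group mean. Between the leaf positions of one treatment and stage, all 6 same-numbered pairs correlated above 0.1 at drought day 0 (0.164 to 0.289), day 6 (0.185 to 0.376) and rehydration 2 h (0.17 to 0.34); the labels do not state that such leaves came from one plant. A fit with that number as a block is given beside comparisons of leaf positions. At drought day 9 the lowest of 5 pairs was 0.0912.

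The alternatives were relative log expression factors in place of TMM, no low-count filter, DESeq2 1.42.0, a required 2-fold change, fits of the compared libraries alone, a block for the replicate number, and each library left out in turn. Fits without the near-empty library, with edgeR and with DESeq2, comparisons between control stages, and the regrouping of same-numbered libraries alike in both leaves were chosen after seeing the data. The groupings of the libraries that were fitted, the real one included, number 10 for each comparison of 3 against 3, 30 for changes between stages and 25 for leaf positions. Plots were drawn with matplotlib 3.10.9.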

Results

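The series followed the leaf transcriptome of the rice cultivar IR64 through a severe drought of 9 days and 6 days of rewatering, beside plants that stayed irrigated. Its title places it in a search for genes that report how strongly rice perceives drought. Gene counts were measured by RNA sequencing in the latest and the second latest leaf at 6 stages, with 3 libraries in each of 24 groups. Total counts per library lay between 6370914 and 24192248 with a median of 13707163, and 23964 to 28607 features had at least 1 count. The 10 most abundant features took 7.02% to 17.2% of the counts. Treated replicate 2 of drought day 9 in the latest leaf held only 1755 counts, so the treated group of that stage rested on 2 usable libraries. The count table gives no gene identifiers, so the responses are described by number, direction, size and course over time, and not by gene.

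Libraries of drought day 9 stood apart from all other stages in both treatments and both leaf positions. The second principal component of the 71 usable libraries carried 15.9% of the variance. On it the 11 libraries of day 9 scored 34.5 to 89.5 and the highest of the 60 others scored 31.6. Controls alone changed too: 4912 features differed between day 9 and day 6 controls in the latest leaf (2374 higher at day 9, 2538 lower). The second latest leaf had 3604 (1966 higher, 1638 lower). Between 2 h and day 9 controls, 4105 features differed in the latest leaf (2015 higher at 2 h, 2090 lower) and 3378 in the second latest leaf (1377 and 2001). Day 6 and 2 h controls differed in 0 features in either leaf by edgeR. At an unadjusted p under 0.05 there were 1177 and 1235, and DESeq2 called 0 and 5. Leaving out day 6 control replicate 3 gave 2 there in the latest leaf, and leaving out day 6 control replicate 1 or 2 gave 1 in the second latest leaf. A required 2-fold change left 2327 and 1980 features in the latest leaf for day 9 against day 6 and 2 h against day 9, and 1597 and 1575 in the second latest leaf. These comparisons of controls were added after the day 9 libraries were seen to stand apart. With relative log expression factors the latest leaf splits became 1940 higher and 3322 lower for day 9 against day 6, and 2569 and 1753 for 2 h against day 9. Counts from the compared libraries alone were 2815 and 2099 in the latest leaf and 2256 for day 9 against day 6 in the second latest leaf. There, leaving out day 6 control replicate 2 gave 2317. Leaving out day 9 control replicate 1 gave 2380 against day 6 and 2031 against 2 h. DESeq2 called 2279 and 1796 in the latest leaf with the near-empty library and 5615 and 4683 without it.

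**Figure D1:**
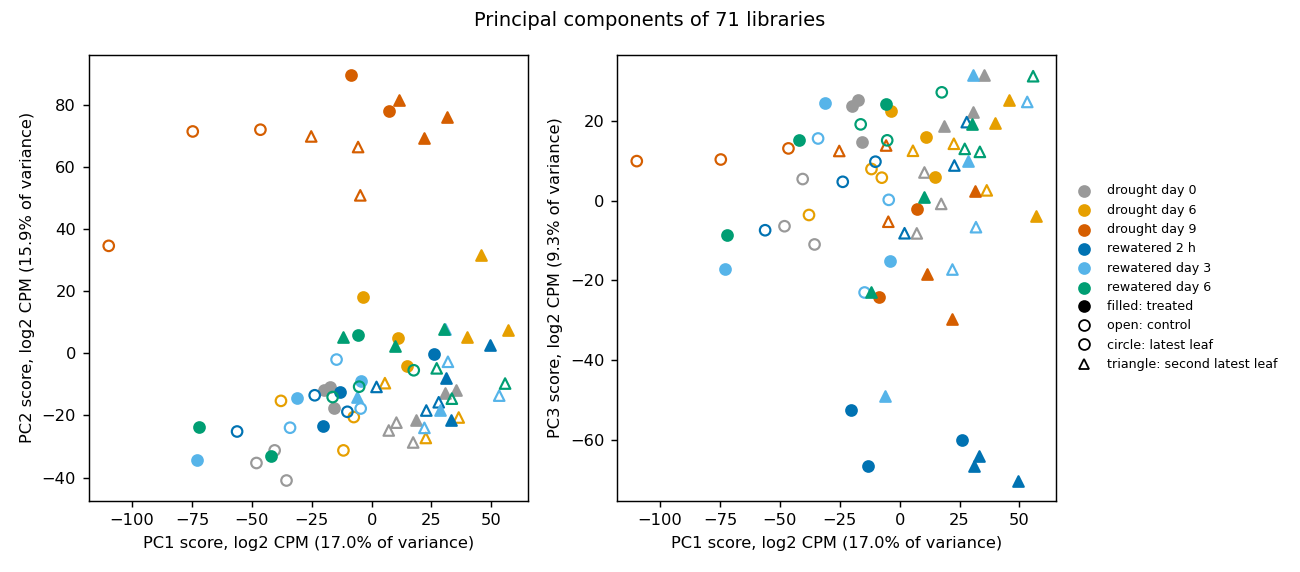
Scores of 71 libraries on the first 3 principal components of log2 CPM, with stages by colour, treated libraries filled and controls open, latest leaf as circles and second latest leaf as triangles. The 11 libraries of drought day 9 lie at 34.5 or more on the second component, above the highest other library at 31.6.

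Leaves of both treatments were also compared at drought day 0, when the treatment began. Of 20599 features tested in the latest leaf edgeR called 120, 47 higher and 73 lower in treated plants, and 2928 had an unadjusted p under 0.05. They had a median log2 fold change of 1.29 for the higher and -1.15 for the lower ones. The higher features took 0.171% ± 0.0186 of the counts in treated plants and 0.0708% ± 0.00923 in controls (SD, n = 3 each). Here and at later stages, the direction of such a gap in shares holds by choice of the features. The shares give size only and are no further evidence of a response. The second latest leaf had 0 of 20950 features called by edgeR, with 2190 at an unadjusted p under 0.05 and 34 by DESeq2. The latest leaf count was 1405 from the 6 libraries alone, 193 without the near-empty library, and 35 by DESeq2 (581 without that library). Leaving out control replicates 1, 2 and 3 in turn gave 6, 53 and 15 and treated replicates 1, 2 and 3 gave 22, 79 and 13. The 6 libraries of the second latest leaf alone gave 76.

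After 6 days of drought, features had risen and fallen in both leaf positions. In the latest leaf 378 features were higher and 274 lower than in irrigated controls (652 called by edgeR), of which 184 and 140 changed at least 2-fold. The higher ones took 1.29% ± 0.104 of the counts against 0.606% ± 0.0489 in controls (SD, n = 3 each). Second latest leaves had 214 higher and 157 lower (371 called), and the higher set took 1.34% ± 0.371 against 0.596% ± 0.0452. More calls were shared than independent lists would share: 63 were higher and 39 lower in both, against 3.88 and 2.06, and 0 were called in opposite directions. The number for independent lists, here and at later stages, ignores deviations that same-numbered libraries of the leaves shared. With relative log expression factors the latest leaf split was 542 higher and 220 lower. Its count was 1888 from the 6 libraries alone, 112 by DESeq2 and 1332 by DESeq2 without the near-empty library. It fell when any of the 6 libraries was left out, to 364, 281 and 154 for control replicates 1, 2 and 3 and to 142, 402 and 235 for treated replicates 1, 2 and 3. The second latest leaf count was 24 from the 6 libraries alone and 765 by DESeq2. It was 221 and 3 without control replicates 2 and 3, and 5, 672 and 128 without treated replicates 1, 2 and 3.

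At drought day 9 features were called in both directions in both leaf positions. The latest leaf had 1017 higher and 1288 lower (2305 of 20599 called, 11.2%), with median log2 fold changes of 0.97 and -1.27. Of these, 785 fell at least 2-fold and 474 rose as far. The lower set took 6.74% ± 0.618 of the counts in treated leaves (SD, n = 2) and 11.7% ± 1.94 in controls (n = 3). Second latest leaves had 256 features higher and 355 lower (611 of 20950 called), and the lower set took 1.098% ± 0.0383 against 2.18% ± 0.375 (n = 3 each). In both leaves 120 features were higher and 212 lower, where independent lists would share 12.3 and 20.6, and 0 went opposite ways. All day 9 libraries, controls included, stood apart from the other stages, as given above. The latest leaf count was 967 from the compared libraries alone and 539 (167 higher, 372 lower) by DESeq2, or 3012 by DESeq2 without the near-empty library. It fell to 909 without control replicate 3, 674 without treated replicate 1 and 733 without treated replicate 3. Fits without treated replicate 1 or 3, here and below, rested on 1 usable treated library beside the near-empty one. Their counts and directions are therefore weak. The second latest leaf count was 348 from the compared libraries alone and 943 by DESeq2. It was 186 and 193 without control replicates 1 and 2, and 222, 208 and 156 without treated replicates 1, 2 and 3.

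**Figure D2:**
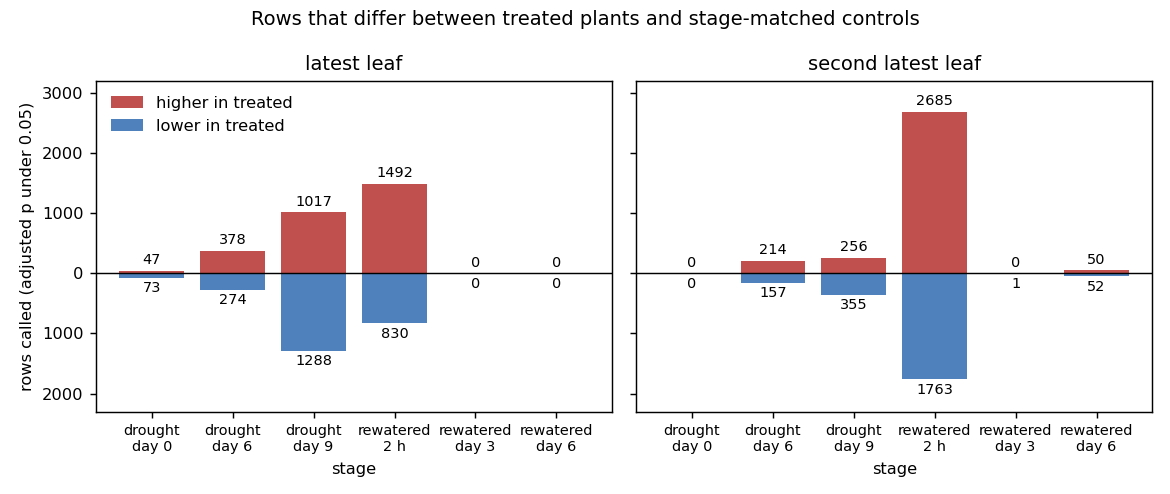
Number of features called by edgeR at each stage, treated against control, in the latest leaf (left) and the second latest leaf (right). Bars above 0 are features higher, and bars below 0 features lower, in treated plants. The counts peak at 2 h of rewatering in the second latest leaf, with 2685 higher and 1763 lower, and are 0 and 1 at rehydration day 3.

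At 2 h after watering resumed, most of the called features were higher in the rewatered plants, and the second latest leaf had its largest count. Second latest leaves had 2685 features higher and 1763 lower (4448 of 20950 called by edgeR, 21.2%), with median log2 fold changes of 0.82 and -0.71. The higher set took 21.8% ± 1.12 of all counts in treated leaves and 11.7% ± 0.428 in controls (SD, n = 3 each), a gap in the direction set by choice of the features. Latest leaves had 1492 higher and 830 lower (2322 of 20599 called), and the higher set took 10.3% ± 1.69 against 4.80% ± 0.319. That count and the 2305 of day 9 did not rank the stages. Day 9 had more with a required 2-fold change (1259 against 851), without the low-count filter (2153 against 1927) and with the replicate block (2059 against 1675). The leaves shared 1268 higher and 514 lower features, against 195 and 70.7 for independent lists, with 0 in opposite directions. The latest leaf count fell to 725 by DESeq2 (3070 without the near-empty library). It fell to 1536 without control replicate 2, 1377 without treated replicate 1 and 1258 without treated replicate 2. The second latest leaf count was 2954 without treated replicate 1.

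Single differences at 2 h were large. Features were eligible if edgeR called them in the latest leaf and the higher group had a mean of at least 10 CPM. Treated and control libraries also had to leave a gap without overlap, and the features with the largest rises and falls were taken. Chance gives such a gap in 10% of comparisons of 3 against 3. The features are known only by their place in the table and were picked at 2 h after the results were seen. Their adjusted p at 2 h in the latest leaf was under 0.05 by choice. Feature 1806 stood at 439 ± 217.5 CPM in rewatered latest leaves and 8.17 ± 4.23 CPM in controls (log2 fold change 5.79, SE 0.689, edgeR adjusted p = 1.61e-06, SD over n = 3). It stood at 439.6 ± 264 against 5.88 ± 2.19 CPM in the second latest leaf (6.25, SE 0.786, adjusted p = 3.33e-06). At drought day 9 it had 58.7 ± 51.4 CPM in treated (n = 2) and 107 ± 86.1 CPM in control latest leaves (n = 3), which was not called (edgeR adjusted p = 0.377). Feature 15548 stood at 16.94 ± 14.66 CPM in rewatered latest leaves and 0.0253 ± 0.0438 CPM in controls, too few counts for a fold (adjusted p = 0.000841). Feature 55464 fell to 3.81 ± 3.36 CPM from 792.9 ± 469.4 CPM in controls (-7.71, SE 1.88, adjusted p = 0.0068), and feature 226 to 0.205 ± 0.245 from 23.4 ± 7.94 CPM (-6.75, SE 1.36, adjusted p = 0.00163). Both had lower fitted values before rewatering, in calls that hung on single libraries. Feature 55464 had a log2 fold change of -8.07 at drought day 6 (edgeR adjusted p = 0.0172) and -5.645 at day 9 (not called, adjusted p = 0.0605). Its day 6 call ended without control replicate 3, treated replicate 1 or treated replicate 3, and its day 9 value ran from -11.81 to -4.139 with single libraries left out. Feature 226 had -4.93 at day 6 (adjusted p = 0.00915) and -7.05 at day 9 (adjusted p = 0.00446). Its day 6 call ended without treated replicate 1 or 3, and its day 9 call without treated replicate 3.

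By 3 days of rewatering edgeR called few differences from irrigated plants, though more features had an unadjusted p under 0.05. Spread within groups (root mean square SD of log2 CPM) was 0.446 in control and 0.524 in treated latest leaves at day 3, against 0.443 and 0.379 at 2 h. In second latest leaves it was 0.508 and 0.522, against 0.353 and 0.375. Few calls at day 3 therefore do not show that treated and control leaves were alike. For the latest leaf edgeR called 0 features at rehydration day 3, with 946 at an unadjusted p under 0.05 and 0 by DESeq2 (2 without the near-empty library). At day 6 edgeR called 0, with 2408 at an unadjusted p under 0.05 and 2 by DESeq2 (222 without that library). The second latest leaf had 1 feature lower at day 3 (log2 fold change -4.21, edgeR adjusted p = 0.00723), with 2132 at an unadjusted p under 0.05. At day 6 it had 102, 50 higher and 52 lower, the higher ones taking 0.543% ± 0.0334 of counts against 0.374% ± 0.0258 (SD, n = 3 each). There 3579 had an unadjusted p under 0.05, beside 3621 and 3751 in that leaf at drought days 6 and 9. Leaving out treated replicate 2 of the latest leaf gave 1 call at day 3 and 516 at day 6, the latter with 350 higher and 166 lower. Fits without the low-count filter or of the 6 libraries alone gave 3 and 1 at day 6 in the latest leaf. The day 3 count of the second latest leaf was 98 without the low-count filter, 91 by DESeq2 and 0 from the 6 libraries alone. Leaving out control replicates 1, 2 and 3 gave 2, 693 and 0 and treated replicates 1, 2 and 3 gave 0, 6 and 0. The day 6 count there was 32 without the filter, 469 by DESeq2 and 0 from the 6 libraries alone. For it, leaving out control replicates 1, 2 and 3 gave 59, 1 and 0 and treated replicates 1, 2 and 3 gave 0, 360 and 0.

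Features called at drought day 9 were followed through rewatering. Of the 2305 features called at day 9 in the latest leaf, 484 were called in the same direction at 2 h (270 higher, 214 lower). Independent lists would share 73.7 and 51.9, and 30 were called in the opposite direction. Of the second latest leaf calls 151 of 611 were called again (45 higher, 106 lower, 24.7%), against 32.8 and 29.9, with 30 opposite, so that the higher set was near the number of independent lists. Across all features, fold changes of day 9 and 2 h correlated with r = 0.408 and 0.312 in the latest and the second latest leaf (exact permutation p = 0.08 and 0.07, both 0.3 when adjusted over 30 pairs of stages), which did not pass 0.05. At days 3 and 6 of rewatering 0 were called again in either leaf by edgeR. In the latest leaf that was fixed, since edgeR called 0 features in all at both days. In the second latest leaf it called 1 at day 3. At day 6 there independent lists would share 0.611 higher and 0.881 lower, and 2 were opposite. These counts of 0 therefore do not show that the day 9 response had ended. DESeq2 gave 0 in either leaf at day 3, and 0 and 11 in the latest and the second latest leaf at day 6. Without the near-empty library it gave 1 at each of these days in the latest leaf. The score of the day 9 features in the latest leaf was 0.605 ± 0.436 in treated and -0.319 ± 0.285 in control libraries at 2 h, and -0.379 ± 0.622 against 0.014 ± 0.336 at day 3 (SD, n = 3 each). For the second latest leaf it was 0.687 ± 0.269 against -0.178 ± 0.101 at 2 h and 0.204 ± 0.413 against 0.371 ± 0.305 at day 3. At 2 h the exact permutation p was 0.1 in both leaves, the smallest 3 against 3 can give, and at day 3 it was 0.4 and 0.7. The latest leaf number still called at 2 h was 65 by DESeq2 (775 without the near-empty library), and 228 without day 9 control replicate 3. It was 105 without day 9 treated replicate 1, and 264 and 291 without 2 h treated replicates 1 and 2. The number in the second latest leaf was 89 without the low-count filter and 249 by DESeq2. It was 46 to 66 when any day 9 library other than control replicate 3 was left out, and 65 to 86 when any 2 h library other than control replicate 1 and treated replicate 3 was left out. In that leaf leaving out day 3 control replicate 2 or day 6 treated replicate 2 gave 5 and 4 still called at those stages, while leaving out day 6 treated replicate 2 in the latest leaf gave 7.

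**Figure D3:**
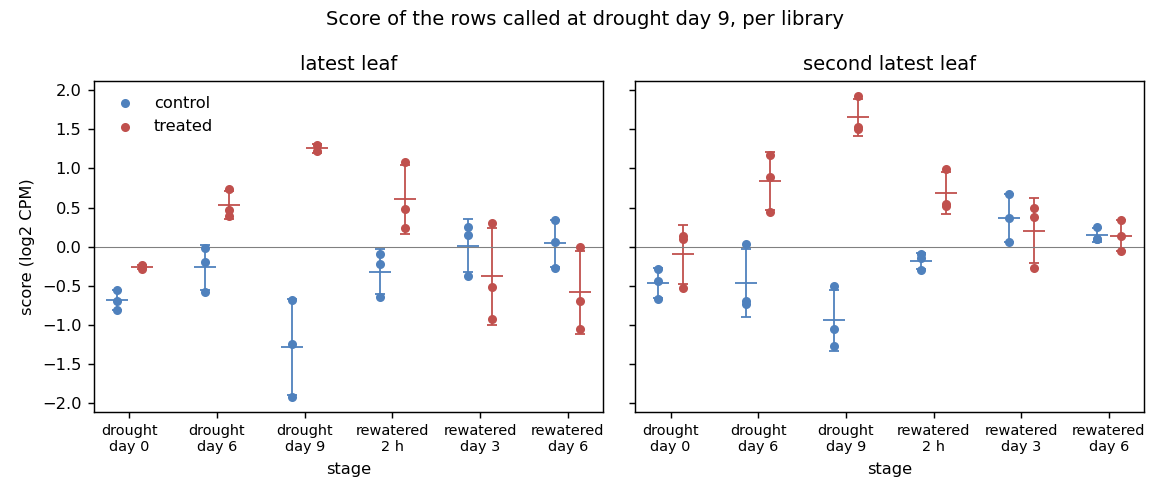
Score of the features called at drought day 9 (mean log2 CPM of those higher minus those lower), per library and stage, with means and bars of 1 SD, in the latest leaf (left, 1017 higher and 1288 lower features) and the second latest leaf (right, 256 and 355). Treated libraries lie above controls at day 6, day 9 and 2 h, and in the latest leaf at day 0, and overlap them at rehydration days 3 and 6; at day 9 the separation holds by choice of the features.

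The change in response between stages was tested within each leaf, and no test compared the leaves in this. From drought day 6 to day 9 the response differed for 194 features in the latest leaf (158 with a larger and 36 with a smaller treated-to-control ratio at day 9) and for 0 in the second latest leaf by edgeR. The latter had 1917 at an unadjusted p under 0.05 and 5 by DESeq2. From day 9 to 2 h it differed for 1560 features in the second latest leaf, 1038 with a larger and 522 with a smaller ratio at 2 h, and for 310 in the latest leaf, 227 larger and 83 smaller. The day 9 to day 6 count in the latest leaf was 119 with relative log expression factors, 17 by DESeq2 (675 without the near-empty library) and 0 from the 12 libraries alone. It was 43, 778 and 12 without day 9 control replicates 1, 2 and 3, 0 and 450 without day 9 treated replicates 1 and 3, and 460, 6 and 2 without day 6 control replicates 1, 2 and 3. It was 2 and 84 without day 6 treated replicates 1 and 2. Leaving out day 6 control replicate 1 in the second latest leaf gave 4. The 2 h to day 9 count in the latest leaf was 133 by DESeq2 (711 without the near-empty library) and 130 from the 12 libraries alone. It was 555 without day 9 control replicate 2, 71 without day 9 treated replicate 3, 196 and 166 without 2 h control replicates 2 and 3, and 139 without 2 h treated replicate 2. The count of 1560 was 909 without day 9 control replicate 2, 978 and 687 without day 9 treated replicates 1 and 3, and 964 and 1012 without 2 h control replicates 2 and 3.

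Fold changes of the latest and the second latest leaf agreed, in part through deviations that same-numbered libraries shared. Fold changes across the 20300 features tested in both correlated with r = 0.61 at drought day 6, 0.61 at day 9 and 0.73 at 2 h, a description across features, which are not independent replicates. Of the features called in the latest leaf, 95.4%, 93.5% and 99.0% had the same sign in the second latest leaf at these stages. At drought day 0 and rehydration days 3 and 6, with at most 120 features called in a leaf, r was still 0.46, 0.39 and 0.33. After the results were seen, same-numbered libraries were regrouped alike in both leaves, and r was taken from mean log2 CPM. At drought day 6, day 9 and 2 h it was 0.599, 0.559 and 0.72, and at most 0.419, 0.498 and 0.529 in the 9 other groupings. At drought day 0 it was 0.468, against at most 0.411 in the others. At rehydration days 3 and 6 it was 0.351 and 0.322, and 3 and 4 of the 10 groupings gave as much. The test of a different response between leaf positions called 0 of 21450 features by edgeR at each of the 3 stages. There were 964, 1726 and 704 at an unadjusted p under 0.05 and 1, 1 and 0 by DESeq2 (2, 3 and 0 without the near-empty library). Larger counts in one leaf are therefore not shown to be a difference between leaves. With the replicate number as a block, 5 features were called at day 6, 1 at 2 h and 186 at day 9, where 1 of 5 replicate pairs of the leaves correlated below 0.1. Leaving out control replicate 2 of both leaves gave 40 at day 9.

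In irrigated plants the leaf positions themselves differed in many features by small amounts. Over the 6 stages 3937 features were higher and 4228 lower in the latest leaf than in the second latest leaf (8165 of 21450 called by edgeR). They had a median absolute log2 difference of 0.38, and 409 and 471 of them differed at least 2-fold. With relative log expression factors the split was 2678 higher and 6261 lower, and by DESeq2 it was 2091 and 4788, or 4274 and 4280 without the near-empty library. The replicate block gave 4823 and 5088.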

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

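The tests of spread between day 9 libraries, reported here, were chosen after the results were seen; those of control changes and of library depth were set beforehand. A different treated-to-control response between stages singled out 3 results by an interaction test in edgeR: 194 features between drought days 6 and 9 in the latest leaf, 310 features between day 9 and 2 h of rewatering in the latest leaf, and 1560 features between day 9 and 2 h in the second latest leaf. Regrouping libraries within the stages cannot decide whether these counts exceed chance, for the reason given below, so chance is not excluded. Of 30 groupings each, the real one included, 5 gave at least 194 (highest other 954), 7 gave at least 310 (highest other 1872) and 4 gave at least 1560 (highest other 3893). None of the 3 counts thus stood out among its groupings. A regrouping that mixes treated and control libraries at only one of the stages, or exchanges them there, leaves the treatment effect of the other stage in the contrast. Whether the groupings with the higher counts were of this kind was not tested. For day 6 against day 9 in the second latest leaf, with 0 called, all 30 groupings gave as many, up to 147.

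The larger response at 2 h than at day 9 in the second latest leaf was weighed against 3 technical explanations. A shift in the controls alone, whose day 9 libraries stood apart, is argued against: 85.2% of the 1560 features moved more in treated plants than in controls between day 9 and 2 h, and the median signed change was 0.87 in treated and -0.13 in control plants (log2). Spread between libraries was 1.07 times as large at day 9 as at 2 h, and thinning the 12 libraries to one total of 11750759 counts left 1431 calls, so neither unequal spread nor depth accounts for it. Of the 1560 features, 1325 were called at 2 h and 126 at day 9, and in the latest leaf 188 of 310 were called at 2 h and 142 at day 9. Called at day 9 and no longer at 2 h were 95 of the 1560, and 111 of the 310 in the latest leaf. With 1325 of the 1560 called at 2 h, a mere return to control levels is argued against for most of them. The regrouping cannot decide whether the counts exceed chance, since a grouping can keep the treatment effect of a stage and which ones did was not tested. No group stayed in drought at 2 h, so whether rewatering itself set off these changes stays open. The hour of harvest is not given in the sources used here, and its part stays open.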

How the results depend on the processing

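The fits without the near-empty library, all values for control stages, scores and single features, and the left-out libraries and the block for features still called after day 9 were chosen after the results were seen. Counts stayed within 1.5 times of the edgeR count in 57.8% of fits for the 20 comparisons. A comparison with no feature called in either fit counted as staying within that range, so the share is lower among fits with calls. The 2 h response stayed within that range in both leaves under relative log expression factors, no filter, the block and the compared libraries alone. The 19 gene list tests could not be run without identifiers. Counts of smaller and larger responses depend on single libraries, and with 3 libraries a group the fits recover few 2-fold changes of a response between stages. Except where fewer libraries or a stricter threshold lowered a count by construction, the cause was not tested.

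A required 2-fold change left 324, 1259 and 851 features in the latest leaf at drought day 6, day 9 and 2 h, 205, 326 and 1461 in the second latest leaf, 47 there at rehydration day 6, 822 for 2 h against day 9 there, and 880 between leaf positions. DESeq2 gave 35, 112, 539 and 725 in the latest leaf at drought days 0, 6 and 9 and 2 h, and 2 at rehydration day 6. It gave 17 and 133 for day 9 against day 6 and 2 h against day 9, and 65 still called at 2 h. For the second latest leaf it gave 34, 765 and 943 at drought days 0, 6 and 9, and 91 and 469 at rehydration days 3 and 6. It gave 5 for day 9 against day 6, 249 and 11 still called at 2 h and rehydration day 6, and 1 and 1 for leaf positions at days 6 and 9. DESeq2 without the near-empty library gave 581 and 1332 in the latest leaf at drought days 0 and 6, and 2 and 222 at rehydration days 3 and 6. It gave 675 and 711 for the changes between stages, 775, 1 and 1 still called at 2 h, day 3 and day 6, and 2 and 3 for leaf positions at days 6 and 9. The reason for the lower DESeq2 counts with that library was not tested. Without it edgeR gave 193 at drought day 0. The compared libraries alone gave 1405, 1888 and 967 in the latest leaf at drought days 0, 6 and 9, 1 at rehydration day 6, and 0 and 130 for the changes between stages. For the second latest leaf they gave 76, 24 and 348 at the drought stages and 0 and 0 at rehydration days 3 and 6. Relative log expression factors gave 119 for day 9 against day 6 in the latest leaf. They moved the median of all fold changes by under 0.1 (log2) in every comparison. Without the low-count filter 3 features were called in the latest leaf at rehydration day 6, and 98 and 32 at days 3 and 6 in the second latest leaf, where 89 were still called at 2 h.

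Treated and control libraries share only a replicate number: 8 of 35 pairs correlated above 0.1, and in 13 of 35 a library correlated best with its own number. With that number as a block, 331 and 1 features were called in the latest leaf at drought day 6 and rehydration day 3, 355 in the second latest leaf at day 9, and 1 of its day 9 features at rehydration day 6. Between leaf positions 31 of 35 pairs were above 0.1 and 33 of 35 best with their own number, and the block gave 5, 186 and 1 differing responses at day 6, day 9 and 2 h, and 9911 features between leaf positions in controls.

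With each library left out in turn, the latest leaf gave 6 to 79, 142 to 402 and 674 to 3174 features at drought days 0, 6 and 9, 1258 to 2379 at 2 h, and 0 to 1 and 0 to 516 at rehydration days 3 and 6. It gave 0 to 778 and 71 to 555 for the changes between stages, and 105 to 670, 0 to 0 and 0 to 7 still called at 2 h, day 3 and day 6. Ranges for the second latest leaf were 0 to 0, 3 to 672 and 156 to 725 at drought days 0, 6 and 9, 2954 to 3970 at 2 h, and 0 to 693 and 0 to 360 at rehydration days 3 and 6. They were 0 to 4 and 687 to 1953 for the changes between stages, and 46 to 162, 0 to 5 and 0 to 4 still called. Leaf positions gave 0 to 0, 0 to 40 and 0 to 0. In the latest leaf, leaving out day 9 treated replicate 1 or 3 left 1 usable treated library there. The median signed change of the day 9 features at drought day 0 in the latest leaf was 0.15 (log2). It ran from -0.017 without day 9 treated replicate 3, where it turned, to 0.291 without treated replicate 1. In the second latest leaf it was 0.11 and ran from -0.018 to 0.194. Of the single features' fits, 94.7% stayed on their side of the adjusted p threshold, where a feature called in neither fit counted as staying. In the second latest leaf at day 9 the call changed in 5 of 6 left-out fits for feature 226 and in 4 of 6 for feature 55464. At 2 h there it changed in 2 of 6 and 0 of 6.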

Other observations

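Scores of the features called at 2 h, the principal components, the scores at other stages and the comparisons of controls were chosen after the results were seen, as were all tests below except 2 at day 0 (the latest leaf libraries alone, scaling by composition) and the regroupings of treated against control libraries and of leaf positions (those made alike in both leaves were chosen after). Features called at 2 h in the second latest leaf scored 1.51 ± 0.139 in treated and -0.259 ± 0.119 in control libraries at that stage. There the separation holds by choice of the features. At drought day 9 the same features scored 0.24 ± 0.303 against -0.0861 ± 0.085 (SD, n = 3 each, two-sided exact permutation p = 0.2). The features called at 2 h in the latest leaf scored 0.394 ± 0.284 in treated (n = 2) and -0.554 ± 0.199 in control libraries (n = 3) at day 9 (exact p = 0.1, the smallest possible). At drought day 0 those of the second latest leaf lay the other way, at -0.335 ± 0.111 in treated and 0.105 ± 0.0917 in control libraries (exact p = 0.1, the smallest 3 against 3 can give), and in the latest leaf at -0.562 ± 0.145 against -0.175 ± 0.131 (exact p = 0.1). At rehydration day 6 the features of the second latest leaf scored -0.181 ± 0.244 against -0.192 ± 0.0188 (exact p = 1).

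On the third principal component, with 9.32% of the variance, the 6 treated libraries of 2 h lay at -52.3 to -70.1. The library nearest to them was treated replicate 2 of rehydration day 3 in the second latest leaf, at -48.9, whose score of the 2 h features was 0.55. Treated replicates 1 and 3 of that group scored -0.358 and -0.361 and the controls 0.0686 to 0.133. Latest leaf treated replicate 2 of the same stage lay at -17.2 on that component with a score of -0.163. No explanation was tested for this library.

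Within treated plants, 5075 features in the latest leaf and 6587 in the second latest leaf changed from day 9 to 2 h, and 3132 and 4353 changed from 2 h to rehydration day 3. From day 3 to day 6 of rewatering 0 and 2 changed by edgeR. In controls, 499 features changed from 2 h to day 3 in the second latest leaf, 464 of them higher at day 3. Called in one direction at all of day 6, day 9 and 2 h were 18 higher and 42 lower features in the latest leaf, and 3 and 19 in the second latest leaf.

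The libraries of day 9 stood apart from the other stages in both treatments. Steady change with plant age is argued against. The labels place the 2 h samples at day 0 of rehydration, so their controls were of nearly the same age as those of drought day 9. Between day 9 and 2 h controls 4105 and 3378 features differed in the latest and second latest leaf by edgeR. Day 6 and 2 h controls differed in 0 features in both leaves, whereas 4912 and 3604 differed between day 6 and day 9. At an unadjusted p under 0.05 day 6 against 2 h had 1177 and 1235. DESeq2 called 0 and 5 (2 in the latest leaf without the near-empty library), and edgeR without the low-count filter called 1 and 4. Depth is argued against by thinning all usable libraries to 6370914 counts. The number called between day 9 and day 6 controls was then 2907 against 3604 in the second latest leaf (80.7%, the lower share) and 4446 against 5482 in the latest leaf, although 1 of the 60 other libraries then reached the day 9 range on the first component. On the second component taken without the 100 most abundant features, 0 other libraries reached the day 9 range. That could hardly have come out otherwise, since on log2 CPM the weight of a feature does not follow its abundance. It draws no conclusion on a few abundant features. A candidate explanation is another hour of harvest, or a batch of libraries, at day 9: all 11 usable day 9 libraries lay beyond every other on the second component, but hour and batch cannot be told apart from each other or from the stage, since the labels give neither. The treated-to-control comparison within day 9 is matched for both only if treated and control plants were handled alike.

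At drought day 0, 120 features of the latest leaf were called, although the treatment had only begun. A fault of the latest leaf libraries alone is argued against, as 96.6% of the features testable in the second latest leaf had the same sign there. When same-numbered libraries were regrouped alike in both leaves, the 120 features of lowest p agreed in sign for 63.4% to 87.3%. Deviations shared by the leaves thus bring much of such agreement, and a difference between the sampled plants of the treatments stays open. Neither the near-empty library (193 calls without it) nor scaling by composition (132 with relative log expression factors) accounts for the calls. The features had the same sign at drought day 6 for 90.8%, at day 9 for 80.8%, at 2 h for 22.5%, and for at most 39.2% at a rehydration day. Relabelling the libraries of these stages gave 6.67% to 93.3% at day 6, 12.5% to 84.2% at day 9, 9.17% to 90.8% at 2 h and 10.8% to 89.2% at rehydration day 6 (exact permutation p = 0.3, 0.3, 0.4 and 0.8 from mean log2 CPM). A drought response already under way at day 0 and a lasting difference between the pots therefore stay open, and the hour between raising the pots and sampling is not given in the sources used here.

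Regroupings of the 6 libraries of a comparison number 10, too few for a share under 0.05. For the latest leaf the real count and the highest other were 120 and 0 at drought day 0, 652 and 0 at day 6, 2305 and 2223 at day 9, 2322 and 0 at 2 h, and 0 and 37 at rehydration day 3 and 0 and 0 at day 6. For the second latest leaf they were 0 and 1 at drought day 0, 371 and 40 at day 6, 611 and 24 at day 9, 4448 and 12 at 2 h, 1 and 1173 at rehydration day 3, and 102 and 0 at day 6. Where more than 1 feature was called, only the real grouping reached its count (1 of 10). All 10 reached the counts of 0, and 9 of 10 reached the count of 1. The grouping with 2223 calls exchanged the near-empty library with control replicate 2. Leaving that control out gave 3174 calls. On the first principal component it lay at -46.4, nearest of the controls (-74.7 and -109.8 for replicates 1 and 3) to the usable treated libraries (-8.67 and 7.11). On the third it lay farthest from them, at 13.1. Whether its position accounts for the calls was not tested. The 1173 calls at rehydration day 3 came from a grouping that set treated replicate 2 with control replicates 1 and 2, and point to a structure of the samples at that stage that treatment does not follow. For control stages the real and highest other counts were 4912 and 302 (day 9 against day 6), 4105 and 26 (2 h against day 9) and 0 and 0 (2 h against day 6) in the latest leaf, and 3604 and 0, 3378 and 2, and 0 and 0 in the second latest leaf. Between leaf positions in controls, 1 of 25 groupings, the real one, gave as many as 8165 features, and the highest other gave 20. That share is under 0.05 and is the smallest that 25 groupings can give, so it argues against chance without excluding it. The groupings exchanged same-numbered leaves, which the labels do not state came from the same plant. For the differences in response between leaf positions, with 0 called, all 25 groupings gave as many, up to 1061, 1909 and 1075 at day 6, day 9 and 2 h. A regrouping that exchanges the leaves of one treatment only turns the contrast into the difference between leaf positions, a structure of the samples.

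Fold changes of stages were also correlated across 21824 features, for 15 pairs of stages in each leaf, 30 in all, with p-values from exact relabelling of the libraries of both stages. The highest r were between drought days 6 and 9, at r = 0.463 and rho = 0.32 in the latest leaf and r = 0.498 and rho = 0.32 in the second latest leaf (exact permutation p = 0.01 each, the smallest possible), and adjusted over the 30 the smallest p was 0.15, so no pair passed. Drought day 9 and rehydration day 6 gave r = -0.403 in the latest leaf (exact permutation p = 0.11, adjusted 0.3). Features are not independent replicates, and these values describe these libraries.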
